A study of Mus musculus with 2 samples.

How the data were processed

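Single-cell RNA was measured in 2 libraries of mouse carotid artery, 1 at 14 days and 1 at 28 days after wire injury. The labels conflict on the vessel: source and design name the carotid artery, the extraction protocol speaks of aortic grafts, and the injury protocol names both the left and the right carotid artery. The carotid artery is taken here as the tissue. Per the labels' protocols, vessels were perfused, the adventitia was dissected from the medial and neointimal layers, the tissue was digested with papain, single live nucleated cells were sorted by flow cytometry, and 10x Genomics libraries were converted for another sequencer. The deposited values are UMI counts per gene and barcode, made by the authors with Cell Ranger 4.0.0 per the file headers and aligned to mm10 per the submitters' processing notes, without normalisation. Listed barcodes start at about 500 UMIs, so emptier barcodes had been removed before deposit. The table has 27998 genes, of which 27645 (98.74%) matched an identifier of GENCODE M21. Gene positions come from that annotation, 1-based, in mm10. The table lists Jchain but no other immunoglobulin and no T cell receptor genes of the lists used. Ccl21a has near-identical copies, so its counts are uncertain.

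Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scanpy 1.11.5 and matplotlib 3.10.9. Cells with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. In each library the highest Scrublet scores were then removed at 0.8% per 1000 barcodes. At 2 weeks these steps removed 54 shallow barcodes, 383 for mitochondrial UMIs and 275 as doublets (4.69%), and at 4 weeks 73, 483 and 587 (6.85%). Scrublet's own threshold called 73 (1.28%) and 264 (3.18%). The kept cells, 5152 and 7422, had medians of 11774.5 and 8708 UMIs and totals of 71759098 and 72753479 UMIs.

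Counts per 10000 were logged, 2000 variable genes were ranked within libraries, and both libraries were clustered together without batch correction, by Leiden at resolution 1 on 30 principal components with 15 neighbours and seed 1. Cluster names come from 26 marker lists. A cluster took the name of the class with the largest share of its markers at 2 or more times the mean of the other clusters and in at least 10% of cells. It needed at least 3 markers and 50% of the list, a lead of 20 percentage points over any other class at 50%, and no more markers of another class than of its own among its top 10 genes by fold. Thymocytes were an exception, because they share T cell markers. A cluster best matched by T cell markers was named thymocyte if it met 50% of the thymocyte list. The lead of 20 points was not asked of thymocyte clusters. Clusters failing this stayed numbered, and their shares are given. The class name "epithelial or thyroid" covers the cluster with thymic epithelial genes.

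With 1 library per time there is no test between times. UMIs were summed per library and class, for classes with at least 100 cells in each library, and scaled to CPM with exact Poisson intervals. The log2 ratio of CPM at 4 weeks over 2 weeks has its exact conditional binomial interval, and shares have exact Clopper-Pearson intervals. A count of 0 was read as allowing up to 3 counts, and a ratio against 0 UMIs uses that floor. For each of 31 gene lists (307 genes, 297 in the table) the median ratio of members with at least 20 UMIs was set among 10000 random lists of the same size, each member drawn from the 100 genes nearest in expression, as a description of these libraries. Intervals of medians come from 2000 Poisson redraws. A member was counted as higher or lower where its own interval excluded 0. Shares of cells with a UMI, and cycling cells (2 or more UMIs of the proliferation list), were taken after thinning each cell to 2700 UMIs, the 10th percentile of kept cells rounded down to a multiple of 100.

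Named genes have at least 50 UMIs in the class, 50 CPM in either library, a log2 ratio of at least 1 in size and an interval that excludes 0. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and unnamed genes were left out, as were genes at under a 10th of their CPM in the highest class, the sign of free RNA. The 5 highest and 5 lowest per class are named, and up to 4 members of each described list with the largest ratios. Dntt in T cell-like cells, Dcn and Fn1, and the genes named to describe clusters, other tissues, follicular helper cells and germinal centre cells, were chosen after their values were seen. Haemoglobin genes are not compared, because 8 barcodes at 4 weeks hold 79.4% of the 113778 haemoglobin UMIs there, against 2459 at 2 weeks in all.

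The filters, clustering settings, marker and gene lists, rule for named genes, thinning rule and most alternatives were fixed before the data were examined. The scoring rule for cluster names, the lists described per class (32 pairs of list and class), the classes that serve as background, the minimum of 50 cells for smooth muscle cell-like cells, the second denominator of shares, the clustering without cell cycle genes, Scrublet's own threshold, the equal weighting of clusters and the medians over members above the free RNA level were chosen after. Left out of the described pairs were modulated smooth muscle, elastic fibre, cartilage and fibrillar matrix genes in smooth muscle cell-like cells, and cartilage genes in fibroblast-like cells, whose direction turned under alternatives. The alternatives were other limits on genes (200, 500) and mitochondrial UMIs (5 and 20%), no doublet removal, Leiden resolutions of 0.5 and 2, 15 principal components, separate clustering, other scalings, thinning and other list minimums.

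The ratio and interval step was tested on simulated counts drawn from the real means and totals, with 200 genes changed in each class. These draws carried counting error only, without variation between cells, animals or libraries. How often the intervals held the true value was thus largely built in. Uneven spread of a gene's UMIs across cells, as seen in the data, was not tested. In the fibroblast-like simulation (2819 genes) all 100 genes changed 2-fold and all 100 changed 4-fold had the right sign and an interval that excluded 0. Of these, 48 and 100 passed the size rule, and the intervals held the true value for 97.0 and 95.0%. In the macrophage-like simulation (2765 genes) 47 and 100 passed the size rule, and in the thymocyte-like one (3219 genes) 51 and 100. In the NK cell-like (2538 genes), T cell-like (2630) and dendritic cell-like (2653) simulations 43, 50 and 44 of the genes changed 2-fold passed it.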

Results

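Cells of remodelled carotid arteries were profiled by droplet single-cell RNA sequencing at 14 and 28 days after wire injury, a model in which a guide wire strips the endothelium and the wall thickens from the inside (intimal hyperplasia). The mice were male C57BL/6J, 8 weeks of age, and the series design gives n = 18 at each time. Each time is 1 library, so no difference between the times has a replicate check, and cells cannot be traced to an animal. The 2-week library held 5864 barcodes with 78773018 UMIs (unique molecular identifiers, counted transcripts), and the 4-week library held 8565 barcodes with 83753250 UMIs. The median barcode had 11038.5 UMIs and 3184 genes at 2 weeks, and 8486 UMIs and 2535 genes at 4 weeks. After filtering, 5152 and 7422 cells remained, in 35 clusters. Of these, 28 clusters carried the markers of 12 cell classes and 7 stayed unnamed. Uninjured arteries were not analysed here. All intervals are 95% intervals and cover counting error only.

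The first comparison asks which cell types made up the kept cells of each library. Macrophage-like cells made up 22.3% of kept cells at 2 weeks (21.2 to 23.5%, 1151 cells) and 4.10% at 4 weeks (3.66 to 4.57%, 304 cells). Neutrophil-like cells were also lower at 4 weeks, at 0.229% (17 cells) against 4.02% (207 cells), and smooth muscle cell-like cells were at 0.984% (73 cells) against 3.92% (202 cells). Fibroblast-like cells were higher, at 43.1% (42.0 to 44.3%, 3200 cells) against 22.2% (21.1 to 23.4%, 1144 cells). B cell-like cells made up 0.815% at 2 weeks (0.588 to 1.10%, 42 cells) and 17.7% at 4 weeks (16.8 to 18.6%, 1311 cells). T cell-like cells made up 3.34% (2.86 to 3.87%, 172 cells) and 11.9% (11.2 to 12.7%, 885 cells). Of these T cell-like cells, cluster 20, led by Cd5, held 126 at 2 weeks and 67 at 4 weeks (2.45 and 0.903% of kept cells). Clusters 7 and 17 held 36 and 10 at 2 weeks, and 591 and 227 at 4 weeks. NK cell-like cells made up 2.85 and 3.79%, dendritic cell-like cells 2.50 and 2.25%, endothelial cell-like cells 0.796 and 0.350%, and plasmacytoid dendritic cell-like cells 0.252 and 0.269%.

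Cells with the gene programme of the thymus were present in both libraries. Thymocyte-like cells, with Rag1 and Dntt, which rearrange antigen receptor genes in developing lymphocytes, made up 24.8% of cells at 2 weeks (23.6 to 26.0%) and 9.23% at 4 weeks (8.58 to 9.91%). A cluster led by Chga and Pth, the parathyroid hormone gene, held 54 cells at 2 weeks and 0 of 7422 at 4 weeks, which allows a share of up to 0.0404%. A cluster led by the airway genes Bpifa1 and Scgb3a2 held 25 and 1 cells, and a cluster with the thymic epithelial genes Tbata and Psmb11 among its top genes held 16 and 1. Pth UMIs were found in other classes too, in 24.2% of thinned fibroblast-like cells at 2 weeks and 5.76% at 4 weeks. The source of these UMIs was not tested. A second denominator left out the thymocyte-like class, the parathyroid, airway and thymic epithelial clusters, and the cell cycle cluster 9. Of the remaining cells, fibroblast-like cells made up 33.3 and 48.4%, macrophage-like cells 33.5 and 4.60%, B cell-like cells 1.22 and 19.8%, T cell-like cells 5.01 and 13.4%, and NK cell-like cells 4.28 and 4.25%. This second denominator was chosen after the values were seen, and the NK cell-like difference is not seen on it. It keeps cluster 24, a cycling cluster of B lineage cells with 1 cell at 2 weeks and 135 at 4 weeks. It also keeps cluster 20 of the T cell-like class, and whether cluster 20 came from thymus was not tested. The clusters it leaves out held 33.3% of cells at 2 weeks and 10.9% at 4 weeks. It cannot set aside fibroblast-like, macrophage-like or other cells of non-arterial tissue. Shares and ratios within classes may thus reflect differing amounts of such tissue. With each library clustered on its own, the NK cell-like share differed by -2.41 percentage points (4 weeks minus 2 weeks) and the macrophage-like share by -9.21 points. Without doublet removal the fibroblast-like shares were 17.9 and 28.5%. All shares are of live, Hoechst-positive sorted cells from vessels whose adventitia was dissected from the inner layers, per the labels' protocols, and the sort and the listed minimum of about 500 UMIs can set them.

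**Figure D1:**
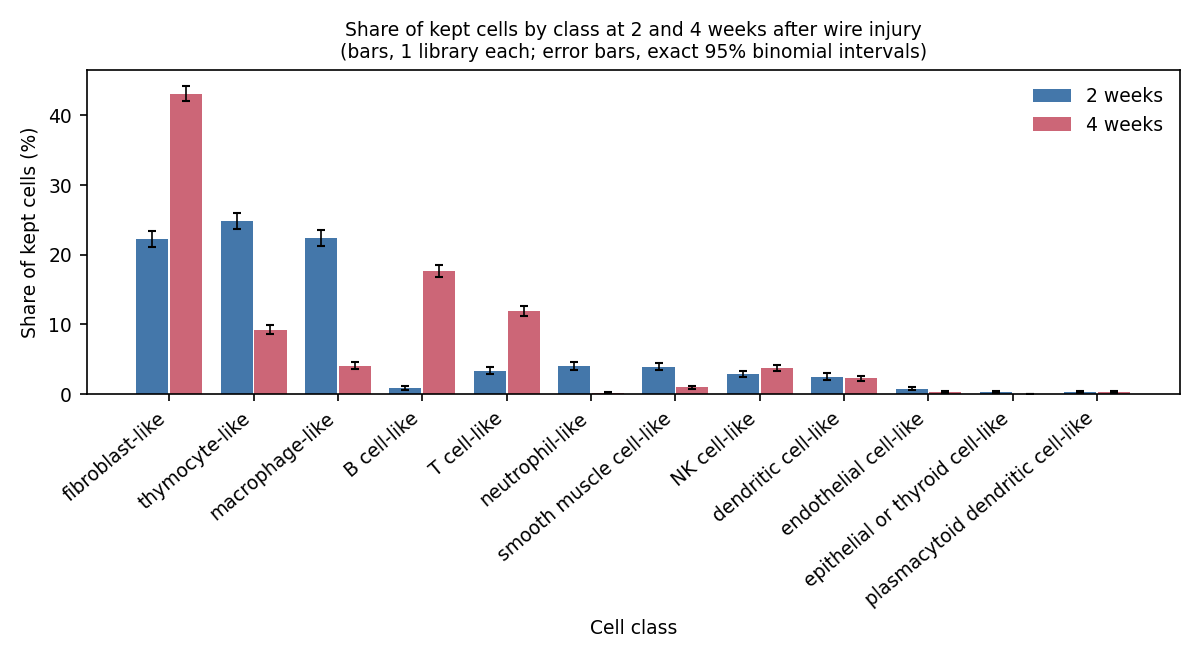
Share of kept cells (%, vertical axis) in each of 12 cell classes (horizontal axis) in the 2-week and the 4-week library; error bars are exact 95% binomial intervals of 1 library each. Macrophage-like cells stand at 22.3 and 4.10%, fibroblast-like cells at 22.2 and 43.1%, and B cell-like cells at 0.815 and 17.7%.

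Within fibroblast-like cells, genes of the fibrillar matrix and of the TGF-beta response had lower levels at 4 weeks. Here and in the other classes the highest and lowest genes are those among genes with at least 50 UMIs in the class, at least 50 CPM in either library and no less than a 10th of their highest class level, and list members outside these limits can lie beyond them. Within these limits the genes with the lowest ratios (log2 of CPM, UMIs scaled to the class total, at 4 weeks over 2 weeks) were Mest at -3.41 (-3.57 to -3.26; 105 and 9.85 CPM) and the non-coding RNA H19 at -3.21 (-3.31 to -3.10; 198 and 21.5 CPM), both imprinted genes of fetal growth. The growth factor gene Ptn (-2.89), the pentraxin gene Ptx3 (-2.86) and the metalloprotease gene Adam12 (-2.73) followed. The highest ratios were those of Inmt, a methyltransferase gene, at 2.31 (2.24 to 2.38; 76.3 and 378 CPM), C7, a complement gene, at 2.23 (2.11 to 2.35; 23.2 and 109 CPM), Ppl (1.37), Galnt15 (1.32) and the matrix gene Comp (1.19). Mest (ENSMUSG00000051855) lies on chromosome 6 from 30723547 to 30748465, H19 (ENSMUSG00000000031) on chromosome 7 from 142575529 to 142578143, Inmt (ENSMUSG00000003477) on chromosome 6 from 55170626 to 55175043 and C7 (ENSMUSG00000079105) on chromosome 15 from 4988762 to 5063740, in mm10.

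Of 12 fibrillar matrix genes, 10 were lower at 4 weeks by more than counting error, Dcn was higher and the interval of Fn1 included 0. Their median ratio was -0.81 (-0.83 to -0.80), at percentile 0 of 10000 random lists matched on expression. The collagen genes Col1a1 (-1.28; 9179 and 3782 CPM), Col3a1 (-1.21; 18550 and 7999 CPM), Col5a1 (-0.97) and Col5a2 (-0.90) had the largest differences. Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042 and Col3a1 (ENSMUSG00000026043) on chromosome 1 from 45311538 to 45349706. Of 12 genes of the TGF-beta response and of myofibroblasts, 10 were lower and 1 was higher, with a median of -0.57 (-0.63 to -0.51; percentile 0). Among them were Cthrc1 (-2.32), Lrrc15 (-1.81) and Acta2 (-2.00), the last at less than a 10th of its level in smooth muscle cell-like cells.

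Elastic fibre genes were divided, with 6 of 11 lower and 4 higher (median -0.36, -0.38 to -0.33; percentile 0.125). Lox, a crosslinking enzyme gene, was at -1.19, Fbn1 at -1.17, Eln, the elastin gene, at -0.90 and Ltbp4 at 0.65. Of 13 measured protease and inhibitor genes, 8 were lower and 4 higher (median -0.28, -0.53 to -0.25; percentile 0.8), among them Adamts4 (-3.34) and Adamts1 (-0.73). Mmp9 (-1.21) and Ctss (-1.05) were at less than a 10th of their level in another class. Immediate early genes, which tissue dissociation also induces, were lower for 11 of 12 (median -0.60, -0.62 to -0.58; percentile 0), with Atf3 at -2.68, Zfp36 at -1.16, Nr4a1 at -0.91 and Ier2 at -0.79.

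Of 11 complement genes, 7 were higher and 4 lower (median 0.21, 0.18 to 0.23; percentile 96.7). The 3 lowest, C1qa (-2.27), C1qb (-2.03) and C1qc (-1.82), were at less than a 10th of their macrophage-like level. Cfb was at -0.44. The complement median turned to -0.11 without doublet removal and to -0.01 at a Leiden resolution of 2. Inflammatory cytokine genes were lower for 11 of 11 (median -2.01, -2.65 to -1.87; percentile 0), but Il1b (-3.57), Ccl3 (-3.37), Nlrp3 (-3.27) and Cxcl2 (-3.20) were at less than a 10th of their level in the highest class. The 4 members above that level had a median of -1.36. Contractile genes of smooth muscle were lower for 12 of 12 in fibroblast-like cells (median -1.90, -1.95 to -1.82), where only Des (-2.84) was above a 10th of its highest class level, and Cnn1 (-3.54), Myocd (-3.27) and Actg2 (-2.71) were not. They were also lower in thymocyte-like cells (median -2.26, -2.63 to -1.70; 7 of 9 lower), where all 9 were below a 10th of their highest class level. Smooth muscle cell-like cells made up 3.92 and 0.984% of the same libraries.

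The largest fibroblast-like cluster differed between the times. At 2 weeks the largest was cluster 6 (473 cells), led by Tnfaip6, Cthrc1 and Postn. At 4 weeks the largest were cluster 1 (1291 cells), led by Pla1a and Pi16, and cluster 3 (1040 cells), led by Mmp3, C7 and Inmt, so Ptx3, Cthrc1, Postn, Col1a1, Col3a1, C7 and Inmt are also among the genes that define clusters. Within cluster 3 the fibrillar matrix median was -0.016 (-0.07 to 0.016) and the TGF-beta median -0.015 (-0.20 to 0.12), and within cluster 6 they were -0.09 (-0.13 to -0.06) and -0.25 (-0.32 to -0.14). Within clusters 1, 10, 12 and 15 the fibrillar matrix medians were -0.49 (-0.53 to -0.45), -0.32, -0.63 (-0.65 to -0.61) and -0.25, and the TGF-beta medians -0.44, -0.37, -0.27 and -0.29. Averaged over 6 clusters with equal weight, the fibrillar matrix median was -0.30, the TGF-beta median -0.27 (-0.90 with each library clustered on its own), the elastic fibre median -0.20, the protease and inhibitor median -0.15, the complement median 0.11 and the contractile median -0.75. The complement median was -0.10 (-0.36 to -0.01) within cluster 1, 0.05 within each of clusters 3 and 6, 0.34 within cluster 10, 0.33 within cluster 12 and -0.03 within cluster 15.

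In macrophage-like cells, genes of antigen presentation were higher at 4 weeks and inflammatory genes were lower, while genes of lipid handling differed in direction between clusters. Within the same limits, the highest ratios were those of the chitinase-like gene Chil3 at 4.67 (4.49 to 4.86; 18.6 and 474 CPM), Retnla at 2.79 (2.71 to 2.87; 138 and 957 CPM), the elastase gene Mmp12 at 2.44, the iron exporter gene Slc40a1 at 2.36 and Itgax at 1.92. The lowest were those of the acute phase gene Saa3 at -3.48 (-3.55 to -3.42; 6873 and 615 CPM), Ptges (-2.90), Cxcl9 (-2.28), Cxcl1 (-2.09) and the interferon-induced gene Rsad2 (-2.08). Chil3 (ENSMUSG00000040809) lies on chromosome 3 from 106147554 to 106167564 and Saa3 (ENSMUSG00000040026) on chromosome 7 from 46711998 to 46715700. At 4 weeks 1 cell held 38.8% of the Saa3 UMIs, 1 held 40.0% of the Cxcl9 UMIs, 1 held 23.3% of the Ptges UMIs and 1 held 20.8% of the Chil3 UMIs. Another held 30% of the Mmp12 UMIs and 1 held 25% of the Rsad2 UMIs. At 2 weeks 1 cell held 23.7% of the Chil3 UMIs. Retnla and Itgax had their highest level in dendritic cell-like cells at both times, Slc40a1 and Rsad2 in neutrophil-like cells, and Cxcl1 in cluster 22. With each library clustered on its own, Cxcl9 turned to 0.47.

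Of 14 genes of lipid-associated macrophages, 9 were higher and 4 lower (median 0.71, 0.67 to 0.74; percentile 100), with Mmp12, Cd9 (1.76), the lipoprotein lipase gene Lpl (1.47) and the osteopontin gene Spp1 (0.96) the largest. All 8 MHC class II genes, which present antigen to T cells, were higher (median 0.49, 0.48 to 0.53; percentile 99.95), among them H2-Eb1 (0.58), H2-Ab1 (0.57), Cd74 (0.50) and H2-Oa (3.47), the last at less than a 10th of its level in another class. The largest cluster was cluster 5 at 2 weeks (625 cells), led by Folr2 and Cd163, and cluster 8 at 4 weeks (145 cells, 446 at 2 weeks), led by Arg1 and Saa3, with Trem2 among its top genes. The lipid-associated median was -0.37 (-0.59 to -0.0086) within cluster 5 and 0.69 (0.64 to 0.76) within cluster 8. It was 0.16 with clusters weighted equally and 0.22 with each library clustered on its own. The MHC class II median was 0.92 (0.87 to 0.97) within cluster 5 and 0.15 (0.11 to 0.23) within cluster 8. It was 0.10 at a Leiden resolution of 2 and 1.61 with each library clustered on its own.

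Inflammatory cytokine genes were lower in macrophage-like cells for 13 of 13 (median -1.34, -1.41 to -1.21; percentile 0), among them Il1a (-2.11), Cxcl1, Ptgs2 (-1.82) and Ccl7 (-1.69). Interferon response genes were lower for 9 of 13 and higher for 1 (median -0.71, -0.85 to -0.55; percentile 0), among them Ifi44 (-3.58), Cxcl9, Rsad2 and Ifit1 (-1.16). Hypoxia and glycolysis genes were lower for 9 of 11 (median -0.47, -0.54 to -0.26; percentile 0.05), with Hif1a at -1.16, Vegfa at -0.78, Tpi1 at -0.63 and Slc2a1 at -0.55. Resident macrophage genes were lower for 6 of 10 and higher for 1 (median -0.23, -0.32 to -0.12; percentile 3.16), with Ccl8 at -1.63, Mrc1 at -0.58, F13a1 at -0.57 and Folr2 at -0.35. Within cluster 5 their median was 0.18 (0.08 to 0.27) and within cluster 8 -0.71 (-0.92 to -0.14). Immediate early genes were lower for 12 of 12 (median -0.79, -0.82 to -0.75; percentile 0), with Atf3 at -1.42, Nr4a1 at -1.40, Egr1 at -1.36 and Ier3 at -1.14.

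Dendritic cell-like cells had lower levels of inflammatory cytokine genes at 4 weeks. The median ratio of the list was -2.41 (-2.66 to -2.21; percentile 0; 12 of 13 lower), with Il6 at -4.24, Ccl4 at -3.21, Cxcl1 at -2.81 and Ptgs2 at -2.75. Of these, only Il6 stood above a 10th of its level in the highest class, and the 4 such members of the list had a median of -2.32. Interferon response genes were lower for 9 of 13 (median -0.88, -1.23 to -0.57; percentile 0), with Cxcl10 at -2.11 (less than a 10th of its highest class level), Ifit1 at -1.76, Oasl2 at -1.35 and Rsad2 at -1.26. The MHC class II median was -0.01 (-0.05 to 0.01; percentile 30.4), with 3 of 8 lower, among them Ciita (-0.58) and H2-Eb1 (-0.12). Values for H2-Oa (0.33) and H2-DMa (0.09) had intervals that included 0. Within cluster 19 the MHC class II median was 0.28 (0.22 to 0.30).

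Immediate early genes were lower for 12 of 12 in dendritic cell-like cells (median -0.88, -1.01 to -0.82; percentile 0), with Egr1 at -2.49, Nr4a1 at -2.44, Atf3 at -1.98 and Dusp1 at -1.18. Within the limits on UMIs and CPM, the highest ratios were those of Insm1 (4.05), Apol7c (3.71), H2-M2 (3.07), AW112010 (2.39) and Serpinb1a (2.38), and the lowest those of the decoy receptor gene Il1r2 (-3.39), Stat4 (-3.18), Jdp2 (-2.87), Gcnt2 (-2.70) and Osm (-2.70). Il1r2, Jdp2, Gcnt2 and Osm had their highest level in neutrophil-like cells at both times, a class at 4.02 and 0.229% of the libraries, and Stat4 in NK cell-like cells. Apol7c and H2-M2 also lead cluster 27, with Ccr7, Fscn1 and Ccl22, which held 23 of 129 dendritic cell-like cells at 2 weeks and 62 of 167 at 4 weeks. Cluster 19, led by Cd209a, held the other 106 and 105. At 2 weeks 1 cell held 57.1% of the Insm1 UMIs and 1 held 48.8% of the Apol7c UMIs, 1 held 37.5% of the H2-M2 UMIs and 1 held 30.3% of the Jdp2 UMIs, and at 4 weeks 1 held 64.3% of the Il1r2 UMIs.

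Smooth muscle cell-like cells, with 73 cells at 4 weeks, were compared under a minimum of 50 cells that was chosen after the counts were seen. The median ratio of their contractile genes was -0.08 (-0.11 to -0.01; percentile 19.5). Of 12 such genes, 3 were higher, 5 lower and 4 had intervals that included 0. Actg2 was at 0.30 and Lmod1 at 0.16, but both were below 0 with at least 500 genes per cell and at a Leiden resolution of 2. The values for Des (-0.50) and Smtn (-0.14) had intervals that included 0. Within the same limits, the highest ratios were those of Lrrtm3 (2.48), the matrix gene Fbln1 (2.26), the tendon transcription factor gene Scx (2.04), Gng2 (2.01) and Adamtsl1 (1.83). The lowest were those of Irs2 (-1.45), Wisp2 (-1.25), Ptprz1 (-1.09), AY036118 (-1.02) and Ext1 (-1.01). At 4 weeks 1 cell held 25.8% of the Fbln1 UMIs and 1 held 23.0% of the Wisp2 UMIs. Fbln1 had its highest level in fibroblast-like cells at both times, a class at 22.2 and 43.1% of the libraries. Gng2 and Adamtsl1 also stood highest outside this class at both times, while Lrrtm3 stood highest within it. The source of the Fbln1 UMIs was not tested.

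**Figure D2:**
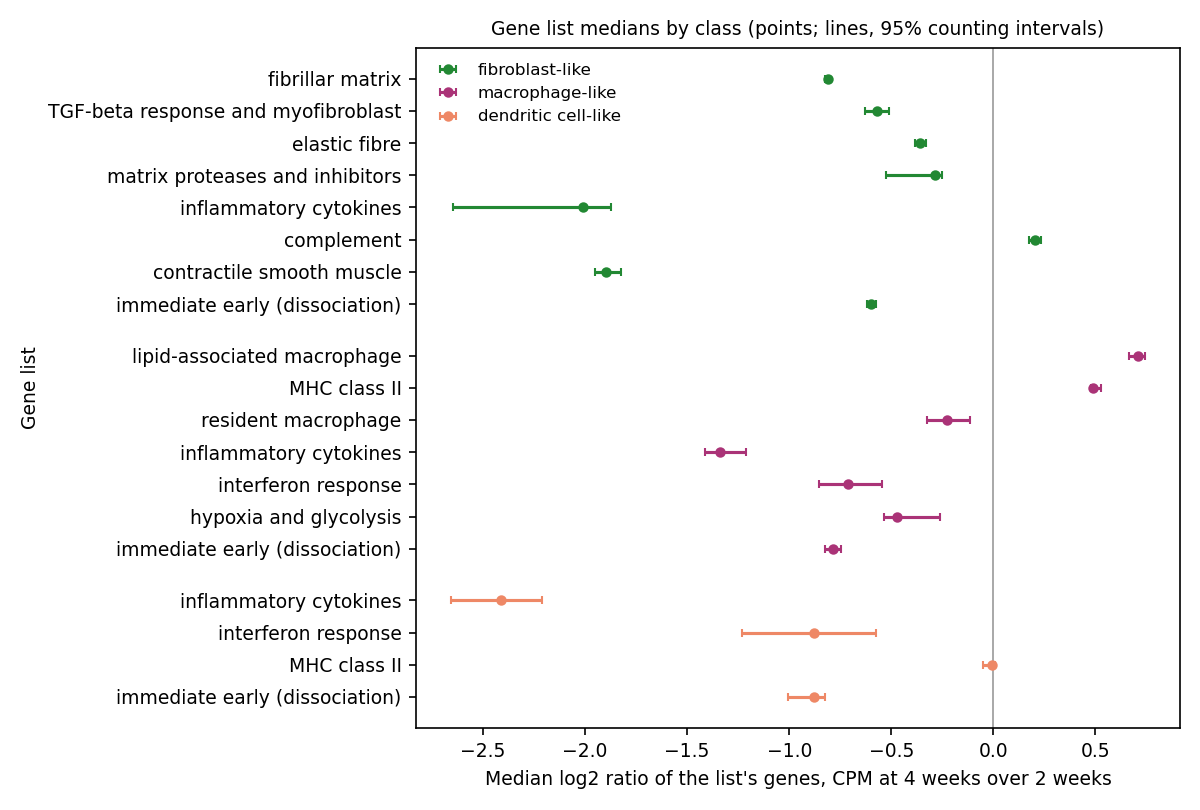
Median log2 ratio of CPM at 4 weeks over 2 weeks (horizontal axis) for the measured genes of each list (vertical axis) in fibroblast-like, macrophage-like and dendritic cell-like cells; points are medians of 1 library per time and lines are 95% counting intervals. Fibrillar matrix genes stand at -0.81 in fibroblast-like cells, lipid-associated genes at 0.71 in macrophage-like cells (-0.37 within cluster 5) and inflammatory cytokine genes at -2.41 in dendritic cell-like cells; the complement median, at 0.21, turned below 0 without doublet removal and at a Leiden resolution of 2.

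Among T cell-like cells, genes with their highest level in thymocyte-like cells, such as Endou, Aqp11 and Myb, had some of the lowest ratios at 4 weeks over 2 weeks. The median ratio of all genes in this class was -0.29, and ratios are given relative to it. Within the limits on UMIs and CPM, the lowest were those of Endou (-3.86), Aqp11 (-3.71), Nrgn (-3.69), Sox4 (-3.55) and Myb (-3.44), and 1 cell held 96.4% of the Nrgn UMIs at 2 weeks. Dntt was detected in 27.1% of thinned T cell-like cells at 2 weeks and in 2.88% at 4 weeks. The highest within them were those of Fam46a (5.84, from 1 UMI at 2 weeks; interval of the uncentred ratio 3.07 to 10.9), Dapl1 (3.26), the NK receptor gene Klrd1 (2.97), Nt5e (2.66) and Nrp1 (2.44). At 2 weeks 1 cell held 45.5% of the Dapl1 UMIs, 1 held 30% of the Klrd1 UMIs and 1 held 22.2% of the Nt5e UMIs. Fam46a had its highest level in fibroblast-like cells at both times, and Nt5e and Nrp1 in endothelial cell-like cells. At 4 weeks Klrd1 stood highest in NK cell-like cells and Dapl1 in T cell-like cells. At 2 weeks the largest cluster was cluster 20 (126 of 172 cells), led by Cd5, with Tox, Lef1 and Ikzf2 among its top genes. At 4 weeks the largest were cluster 7 (591 of 885), led by Dapl1, and cluster 17 (227, against 10 at 2 weeks), with Pdcd1, Icos and Cxcr5 among its top genes. The gene lists of this class include genes that define these clusters.

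Of 6 regulatory T cell genes, 3 were higher and 2 lower in T cell-like cells before centring (centred median 0.75; percentile 99.6), with Foxp3, the lineage transcription factor gene, at 3.42 and Il2ra at 2.62, from 2 and 3 UMIs at 2 weeks, and Ikzf2 at -1.69 and Ctla4 at -0.52. Of 6 measured cytotoxic genes, 3 were higher and 1 lower (centred median 1.66; percentile 99.97), with Nkg7 at 1.80, Prf1 at 3.48 from 1 UMI at 2 weeks and Gzma at -3.93. All counts of higher or lower genes in this class are from before centring. Il2ra, Gzma, Ifng and Lag3 were at less than a 10th of their highest class level. The value for Ifng (2.03) had an uncentred interval that included 0. With at most 5% mitochondrial UMIs per cell, both lists turned, to uncentred medians of -1.87 and -0.71, as did Foxp3 (-1.52), Il2ra (-2.06) and Lag3 (-1.93), uncentred. Naive lymphocyte genes were divided, with Klf2 (1.48) among 3 higher and Tcf7 (-1.18) and Lef1 (-0.97) among 3 lower, and their uncentred median of -0.24 became 0.05 after centring. Of 8 genes of activation and exhaustion, 2 were higher and 2 lower, with Tox at -2.02. Their uncentred median of 0.29 had an interval that included 0 (-0.14 to 0.48), and it was -0.31 over the 5 members above a 10th of their highest class level. Pdcd1 was at 0.85 with an uncentred interval that included 0. Lag3 had 0 UMIs at 2 weeks and 37 at 4 weeks, an uncentred ratio of 0.72 against a floor of 3 UMIs, with a lower counting limit of 0.35. On thinned cells the ratio against that floor was -0.07, which leaves the direction open.

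NK cell-like cells, a class whose name is uncertain, had lower proliferation and higher naive lymphocyte genes at 4 weeks. The median ratio of all genes was -0.20, and ratios are again relative to it. Counts of genes higher or lower are from before centring. Proliferation genes were lower for 16 of 16 (median -3.20; percentile 0), with Nusap1 at -5.86 from 1 UMI at 4 weeks (less than a 10th of its highest class level), Ube2c at -5.66, Cenpf at -5.61 and Birc5 at -5.41. Hist1h1b (-4.52) and Ccnb2 (-4.17) were also among the 5 lowest genes within the limits on UMIs and CPM. Of 147 cells at 2 weeks, 1 cell held 26.6% of the Ube2c UMIs, 1 held 25.3% of the Cenpf UMIs, 1 held 21.7% of the Birc5 UMIs, 1 held 30.7% of the Hist1h1b UMIs and 1 held 20.9% of the Ccnb2 UMIs. Naive lymphocyte genes were higher for 6 of 6 (median 1.23; percentile 100), with the homing receptor gene Ccr7 at 3.65, Klf2 at 1.44 and Tcf7 at 1.02. Nsg2 (3.29), Treml2 (2.74) and Pde2a (1.94) were also among the 5 highest genes within them, and 1 cell held 75.0% of the 8 Ccr7 UMIs and 1 held 40.0% of the 10 Nsg2 UMIs at 2 weeks. Ccr7 had its highest level in dendritic cell-like cells at both times, Nsg2 in thymocyte-like cells and Pde2a in endothelial cell-like cells. Cytotoxic genes were lower for 7 of 8 (median -0.43; percentile 0.250), with Gzmk at -1.72, Fasl at -1.69, Gzmb at -0.82 and Ifng at -0.46. Genes of activation and exhaustion were lower for 5 of 9 (median -0.44; percentile 1.05), with Havcr2 at -4.56, Ctla4 at -2.41, Icos at -2.10 and Pdcd1 at -2.05. Over the 7 members above a 10th of their highest class level the uncentred median was -2.25, against -0.64 over all 9. Most of the class was cluster 11 (132 and 240 cells), led by Ly6c2, Cxcr3 and Nkg7, within which the uncentred cytotoxic median was -1.21, against -0.63 in the class. Cluster 30, with Ncr1, Gzma and Prf1 among its top genes, held 15 and 41 cells. In several alternative settings too few cells kept the name to be compared (23 and 49 without doublet removal).

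Thymocyte-like cells had lower proliferation genes at 4 weeks for 16 of 16 (median -0.46, -0.55 to -0.42; percentile 0), with Tpx2 at -0.81, Nusap1 at -0.70, Ccnb1 at -0.68 and Top2a at -0.61. Their median was -0.19 with the clusters of the class weighted equally, -0.43 (-0.69 to -0.10) within cluster 2 and 0.06 (-0.03 to 0.11) within the cycling cluster 13. Cluster 13 held 19.2% of the class at 2 weeks and 10.5% at 4 weeks, and the cycling cluster 26 held 5.56 and 2.19%. Cholesterol synthesis genes were lower for 5 of 8 (median -0.59, -0.75 to -0.41; percentile 0), with Hmgcs1 at 59.5 and 29.8 CPM and Sqle at -0.72. The value for Lss (-0.72) had an interval that included 0. Immediate early genes were higher for 8 of 12 and lower for 4 (median 0.39, 0.30 to 0.47; percentile 100), with a median of 0.60 over members above a 10th of their highest class level. Fosb (1.23), Klf4 (1.22), Cd52 (1.14), Ier5 (1.12) and Jun (1.07) had the highest ratios within the limits on UMIs and CPM, and Acsl3 (-1.26), Vps37b (-1.15), Gpr171 (-1.13), Per1 (-1.10) and Nr4a1 (-1.06) the lowest. At 4 weeks Cd52 had its highest level in B cell-like cells, Klf4 in fibroblast-like cells, Ier5 in neutrophil-like cells, and Fosb and Jun in cluster 22. Atf3 (-3.17) and Ier3 (-1.25) were at less than a 10th of their highest class level. Cluster 2 was the largest at both times, with 792 and 450 cells.

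After each cell was thinned to 2700 UMIs, 44.7% of thymocyte-like cells at 2 weeks (41.6 to 47.9%) and 33.2% at 4 weeks (28.4 to 38.4%) had at least 2 UMIs of proliferation genes. These are shares of 988 of the 1278 cells of the class at 2 weeks and of 358 of 685 at 4 weeks. The cells left out were the shallow ones, while the cycling cluster 13 had medians of 13157 and 10443 UMIs. Without thinning the shares were 43.7 and 27.2%, but thinned to the 25th percentile of depth the difference was 0.0587 percentage points, and it was -4.56 points with at most 5% mitochondrial UMIs. The share was 19.9% (13.7 to 27.3%) and 8.82% (5.74 to 12.8%) of NK cell-like cells, and 14.3% (8.95 to 21.2%) and 7.31% (5.64 to 9.30%) of T cell-like cells. Unthinned shares were 56.5 and 34.2% of NK cell-like cells, and 29.7 and 24.5% of T cell-like cells. Thinned to the 25th percentile, the differences were -24.7 and -14.3 percentage points. The thinned shares were 17.3 and 9.49% of dendritic cell-like cells, 5.88 and 4.96% of macrophage-like cells, 2.65 and 1.41% of fibroblast-like cells, and 20.0% of 35 and 14.7% of 1241 B cell-like cells, with unthinned shares of 56.6 and 38.9%, 38.1 and 24.0%, 41.7 and 18.2%, and 33.3 and 30.5%. The fibroblast-like difference turned to 0.190 percentage points with at least 500 genes per cell. Cycling cells also formed clusters of their own, so these shares leave out part of them. Cluster 9, led by Rrm2 and Tyms, held 343 cells at 2 weeks and 124 at 4 weeks. Cluster 24, best matched by B cell markers but outside the B cell-like class, held 1 and 135. All 126 of its thinned cells at 4 weeks counted as cycling. The B cell-like shares thus do not show a fall in cycling among all B lineage cells. Thinning left out 540 cells at 2 weeks and 699 at 4 weeks.

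The series title names tertiary lymphoid organs, ectopic lymphoid tissue with B and T cell areas, so the genes of lymphoid organ formation were compared as shares of thinned cells with a UMI. Lymphotoxin gene Ltb was detected in 80.2% of T cell-like cells at 4 weeks (77.3 to 82.9%) and in 52.1% at 2 weeks (43.5 to 60.7%), against 1.58 and 0.0915% of fibroblast-like cells. Cxcr5, the receptor that guides cells to B cell follicles, was detected in 5.52% of T cell-like cells at 4 weeks (4.07 to 7.29%) and in 0 of 140 at 2 weeks, which allows up to 2.14% of cells with a UMI. The clusters of this class differ between the times, with cluster 20 holding 73.3% of it at 2 weeks and 7.57% at 4 weeks, and Cxcr5 is among the top genes of cluster 17, so these differences are not separated from the mix of clusters. Il7r was detected in 41.0 and 21.4% and Ccr7 in 301 of 834 and 42 of 140 T cell-like cells at 4 and 2 weeks. At 4 weeks 86.6% of B cell-like cells had Ltb, 46.1% had the complement receptor gene Cr2, 19.7% had Cxcr5 and 8.14% had Lta. Only 35 B cell-like cells were deep enough at 2 weeks.

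In fibroblast-like cells, Cxcl13, the ligand of Cxcr5, was detected in 5.76% at 2 weeks (4.46 to 7.31%; 87.9 CPM) and in 7.86% at 4 weeks (6.93 to 8.88%; 153 CPM), against 0 of 35 and 0.886% of B cell-like cells. A count of 0 of 35 allows up to 8.57%, more than 5.76%, so it sets no background for Cxcl13 at 2 weeks. Cxcl13 (ENSMUSG00000023078) lies on chromosome 5 from 95956951 to 95961068. Cxcl12 was detected in 44.5% (41.5 to 47.5%) and 34.6% (32.9 to 36.3%), against 0 of 35 and 1.69% of B cell-like cells. Tnfsf13b, the B cell survival factor gene, was detected in 5.86% (4.54 to 7.42%; 27.0 CPM) and 10.0% (8.96 to 11.1%; 42.6 CPM) of fibroblast-like cells, but without thinning in 33.8 and 33.5%. Ccl19 was detected in 7.14% (5.68 to 8.83%) and 5.53% (4.74 to 6.40%), and Ltbr in 11.6 and 10.3%. Tnfsf13b, Ccl19, Ltbr and T cell-like Cxcr5 are given without a background share. Unthinned shares of Cxcl13 were 10.1 and 11.8%, of Cxcl12 76.9 and 60.9%, of Ccl19 26.1 and 16.4%, and of T cell-like Ltb 60.5 and 91.2% and Cxcr5 0.581 and 9.38%. The median depth of fibroblast-like cells was 21140 UMIs at 2 weeks and 12493 at 4 weeks, of T cell-like cells 4224 and 6809, and of B cell-like cells 4704.5 and 4653. Of the genes of high endothelial venules, Glycam1 was detected in 2 and Madcam1 in 1 of 41 endothelial cell-like cells at 2 weeks and neither in 25 at 4 weeks, while Gcnt1 was detected in 0 of 41 and 4 of 25 (4.54 to 36.1%).

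**Figure D3:**
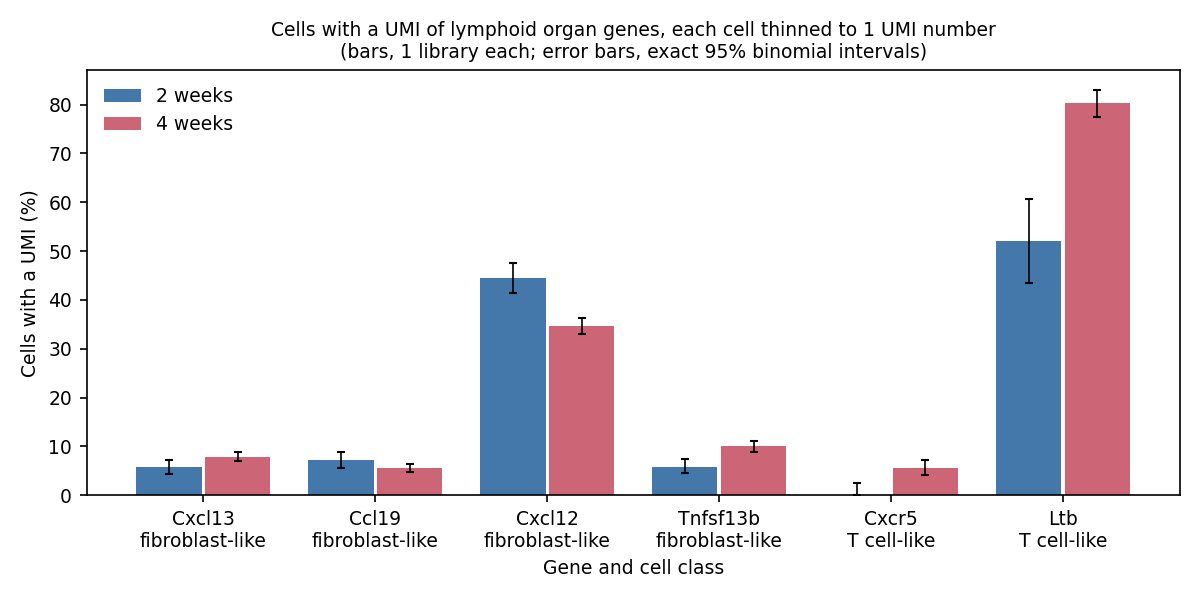
Share of cells with at least 1 UMI (%, vertical axis) of 6 lymphoid organ genes in the named class (horizontal axis) at 2 and 4 weeks, each cell thinned to 2700 UMIs; error bars are exact 95% binomial intervals of 1 library each. Ltb in T cell-like cells stands at 52.1 and 80.2%, Cxcr5 at 0 of 140 cells and 5.52%, and Cxcl12 in fibroblast-like cells at 44.5 and 34.6%; Tnfsf13b, at 5.86 and 10.0%, was at 33.8 and 33.5% without thinning.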

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

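Each result was recomputed under every alternative that gave a value, changing 1 choice at a time, except that the setting of at least 200 genes also drops the UMI minimum. The second denominator of shares, the minimum of 50 cells that admits smooth muscle cell-like cells, the clustering without cell cycle genes, Scrublet's own threshold, the equal weighting of clusters and the medians over members at or above 0.1 of their CPM in the highest class were tests chosen only after the results were seen. A value is called moved where it left the counting interval of the reported value, and reversed where the sign changed and that interval excludes 0. Of 107 values of class shares, 68 stayed within that interval, 37 moved and 2 reversed, and 100 kept their direction. Of 86 values of the 5 leading list medians (fibrillar matrix, TGF-beta response, MHC class II, lipid-associated macrophage and dendritic cell-like inflammatory cytokine genes), 48 stayed, 38 moved and 0 reversed. Of 429 values of the 27 other list medians, 313 stayed, 110 moved and 6 reversed. This count leaves out 5 pairs of list and class that were not described because their direction turned under alternatives, so it understates how often list medians reverse. Of 2344 values of 186 named gene ratios, 1886 stayed, 449 moved and 9 reversed. Of 73 values of cycling shares, 64 stayed, 7 moved and 2 reversed, and of 78 values of lymphoid gene shares, 69 stayed, 8 moved and 1 reversed. Across the alternatives, differences in share (4 weeks minus 2 weeks, in percentage points) ranged from 10.6 to 22.1 for fibroblast-like cells, from -28.9 to -9.21 for macrophage-like cells, from 14.2 to 18.6 for B cell-like cells, from 8.31 to 8.93 for T cell-like cells and from -5.77 to -3.45 for neutrophil-like cells. In several settings fewer than the minimum of NK cell-like, dendritic cell-like or smooth muscle cell-like cells kept the name, and these gave no values. Where no cause is named below, the cause was not tested. Depth limits the thinned shares, which leave out 540 cells at 2 weeks and 699 at 4 weeks. The median of all measured genes lay at -0.29 in T cell-like and -0.20 in NK cell-like cells, against at most 0.06 in size in the other classes.

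Among cells outside the thymocyte-like, parathyroid, airway and thymic epithelial clusters and the cycling cluster 9, the denominator itself is smaller. There the share differences were 15.1 points for fibroblast-like, -28.9 for macrophage-like, 18.6 for B cell-like, -0.0277 for NK cell-like, -1.23 for dendritic cell-like, -4.77 for smooth muscle cell-like and -5.77 for neutrophil-like cells. Without doublet removal they were 10.6 for fibroblast-like, -17.5 for thymocyte-like, 18.0 for B cell-like, 0.188 for NK cell-like, 0.582 for dendritic cell-like and -3.55 for smooth muscle cell-like cells. With each library clustered on its own they were 13.02 for fibroblast-like, -20.6 for thymocyte-like, -9.21 for macrophage-like, 15.0 for B cell-like, -2.41 for NK cell-like and -3.94 for smooth muscle cell-like cells. At a Leiden resolution of 2 they were 17.9 for fibroblast-like, -15.1 for macrophage-like and 0.214 for NK cell-like cells, and at 0.5 they were -20.9 for thymocyte-like and 15.0 for B cell-like cells. Clustered without cell cycle genes, they were -17.6 for thymocyte-like, 15.0 for B cell-like and 0.226 for NK cell-like cells. With at most 5% mitochondrial UMIs they were -21.2 for thymocyte-like, 14.2 for B cell-like, 0.251 for NK cell-like and -2.27 for smooth muscle cell-like cells, and with at most 20% they were 15.3 for B cell-like and -3.58 for smooth muscle cell-like cells. With at least 500 genes they were 15.1 for B cell-like and 0.234 for NK cell-like cells, with 200 genes and no UMI minimum 0.227 for NK cell-like cells, with 15 principal components 15.2 for B cell-like cells, and with Scrublet's own threshold 18.1 for B cell-like and 0.216 for NK cell-like cells.

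The fibrillar matrix median in fibroblast-like cells was -0.77 with CPM free of mitochondrial, ribosomal protein and haemoglobin genes, -0.76 on thinned cells, -0.30 with clusters weighted equally, -0.85 with at most 20% mitochondrial UMIs, -0.94 without doublet removal, -0.89 at a resolution of 2, -0.83 with 15 principal components, -0.97 with separate clustering and -0.80 clustered without cell cycle genes. The TGF-beta median was -0.70 on thinned cells, -0.47 over members at or above 0.1 of their CPM in the highest class, -0.27 with clusters weighted equally, -0.71 with at least 500 genes, -0.75 with at most 5% mitochondrial UMIs, -0.50 without doublet removal, -0.47 at a resolution of 2, -0.90 with separate clustering and -0.69 with Scrublet's own threshold. The complement median reversed to -0.11 without doublet removal and to -0.0086 at a resolution of 2.

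In macrophage-like cells the MHC class II median was 0.54 with the reduced CPM, 0.47 centred on all genes, 0.46 on thinned cells, 0.54 with clusters weighted equally, 0.41 without doublet removal, 0.10 at a resolution of 2, 0.44 with 15 principal components, 1.61 with separate clustering and 0.44 with Scrublet's own threshold. The lipid-associated median was 0.76 with the reduced CPM, 0.65 on thinned cells, 0.16 with clusters weighted equally, 0.65 with at most 20% mitochondrial UMIs, 0.58 without doublet removal, 0.90 at a resolution of 2, 0.22 with separate clustering and 0.65 with Scrublet's own threshold. With separate clustering Cxcl9 reversed to 0.47. The dendritic cell-like inflammatory cytokine median was -2.20 on thinned cells, -1.72 with 15 principal components and -2.09 with Scrublet's own threshold.

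In T cell-like cells, with at most 5% mitochondrial UMIs, Lag3 reversed to -1.93, Foxp3 to -1.52, Il2ra to -2.06, the regulatory T cell median to -1.87 and the cytotoxic median to -0.71. On thinned cells Lag3, with 0 UMIs at 2 weeks, was at -0.072 against the floor. That value is counted among the 9 reversed ratios, although thinning only lowers the 4-week count against a fixed floor and no change of direction is shown. The naive lymphocyte median reversed to 0.078 with the reduced CPM and to 0.052 centred on all genes, which by construction removes the shift of all genes. In smooth muscle cell-like cells Actg2 and Lmod1 reversed to -0.0027 and -0.20 with at least 500 genes, and to -0.0055 and -0.20 at a resolution of 2.

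Differences in cycling share without thinning were -23.5 points for fibroblast-like, -14.0 for macrophage-like, -22.3 for NK cell-like and -17.7 for dendritic cell-like cells. Thinned to the 25th percentile they were 0.0587 for thymocyte-like, -14.3 for T cell-like and -24.7 for NK cell-like cells. With at most 5% mitochondrial UMIs the thymocyte-like difference was -4.56, and with at least 500 genes the fibroblast-like one reversed to 0.190. Differences in lymphoid gene detection without thinning were -9.76 for Ccl19, -16.0 for Cxcl12 and -0.329 for Tnfsf13b in fibroblast-like cells and 8.80 for Cxcr5 in T cell-like cells, where depth differs between the libraries. The fibroblast-like difference was -13.7 for Cxcl12 and 1.90 for Tnfsf13b without doublet removal, -14.7 for Cxcl12 at a resolution of 2, and 4.19 for Cxcl13 and -14.3 for Cxcl12 with separate clustering.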

Other observations

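Of the tests below, those of blood lymphocytes and of thymus tissue were chosen only after the result was seen, and the genes of follicular helper and germinal centre cells were picked for description after the data were seen. Germinal centre-type clusters held 4 of 43 B lineage cells at 2 weeks (9.30%, 2.59 to 22.1%) and 275 of 1446 at 4 weeks, shares whose intervals overlap. Cluster 23, with Mzb1 and Rgs13 among its top genes, held 3 cells at 2 weeks and 140 at 4 weeks. Cluster 24, whose leading genes were Jchain, Pou2af1 and Rgs13, held 1 and 135 (1.82% of cells, 1.53 to 2.15%). At 4 weeks 57.9% of thinned cluster 24 cells had an Rgs13 UMI, 26.2% a Bcl6 UMI and 24.6% an S1pr2 UMI, against 0.296, 7.11 and 6.61% of fibroblast-like cells, and all 126 counted as cycling. Mef2b was detected in 0 of these 126 cells and Cxcr5 in 6.35%, against 19.7% of B cell-like cells, and Bcl6 was also detected in 28.0% of cluster 34 and 18.9% of neutrophil-like cells at 2 weeks. Of thinned T cell-like cells, 2.16% at 4 weeks and 0.714% at 2 weeks had a UMI of Il21, a helper cytokine gene (intervals 1.28 to 3.39% and 0.0181 to 3.92%, which overlap), against 0 of 3039 and 0 of 1093 fibroblast-like cells. For Cd40lg the shares were 7.91 and 3.57%, for Pdcd1 6.71 and 3.57% and for Icos 15.8 and 19.3%. Bcl6 was lower at 4 weeks, detected in 5.52% (4.07 to 7.29%) against 12.1% at 2 weeks (7.24 to 18.7%). These intervals overlap only from 7.24 to 7.29%. Overlap of 2 intervals alone does not show that the shares are alike. Cluster 20 held 73.3% of the class at 2 weeks and 7.57% at 4 weeks, so these shares are not separated from the mix of clusters.

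Other clusters that kept a number held few cells at each time. Cluster 21, with Il17a and Cd163l1 among its top genes, held 1.67% of cells at 2 weeks and 1.37% at 4 weeks, and cluster 22, led by Apod and Myoc, 1.49 and 0.930%. In cluster 22 Cxcl13 was detected in 1 of 75 thinned cells at 2 weeks and in 9 of 62 at 4 weeks. Cluster 32, led by Mmrn1, Cldn5 and Prox1, held 24 and 21 cells. Of these, 20 of 24 at 2 weeks and 17 of 21 at 4 weeks had a UMI of Ccl21a, the chemokine gene of lymphatic endothelium, whose near-identical copies make its count uncertain, and 5 and 8 had Il7. Bpifa1 was detected in 80.0% and Scgb3a2 in 96.0% of the 25 thinned cells of cluster 34 at 2 weeks.

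B cell-like cells made up 0.815 and 17.7% of the libraries, and blood lymphocytes or cells of a lymph node are the technical explanations weighed. Germinal centre clusters, a state that circulating B cells lack, held 19.018% (17.025 to 21.137%) of 1446 B lineage cells at 4 weeks, over the 1% bound set for blood, which argues against blood as the whole source. Sinus macrophage genes (Siglec1, Cd5l, Marco, Timd4) reached 2 UMIs in 1.145% of 262 macrophage-like cells at 4 weeks (0.237 to 3.31%) and in 2.80% of 1072 at 2 weeks (1.90 to 3.97%). These intervals overlap, and of endothelial cell-like cells Glycam1 was detected in 0 of 25 at 4 weeks and 2 of 41 at 2 weeks but Gcnt1 in 4 and 0, too few to decide, so a lymph node collected with the 4-week tissue and lymphoid tissue of the vessel wall cannot be told apart. The difference in time after injury stays open as an untested biological explanation.

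Thymocyte-like cells made up 24.8 and 9.23% of the libraries, and free RNA of other cells and thymus tissue collected with the artery are the explanations weighed. The lowest ratio of detection, thymocyte-like over fibroblast-like cells, for Rag1 and Ptcra in either library was at least 42.4. Ptcra was detected in 0 of 1093 fibroblast-like cells at 2 weeks. Free RNA would give a like share in every class, but both genes are among the markers that named the class. Their higher share there is thus in part built in and is no independent test against free RNA. At 2 weeks 56.3% and at 4 weeks 64.2% of thinned thymocyte-like cells had UMIs of both Cd4 and Cd8a, against 7.14 and 1.68% of T cell-like cells. Of 8 genes on the list for thymus tissue collected with the artery, 5 were at 10 or more times the mean of the other clusters in 1 cluster, of 16 cells at 2 weeks and 1 at 4 weeks, with Foxn1 in 7 and Psmb11 in 9 of 14 thinned cells at 2 weeks. Thymus tissue collected with the artery is thus a likely source of these cells, and because this rests on a test chosen after the cells were seen, it remains a hypothesis, beside which no biological explanation was tested.

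Fibrillar matrix genes had a median ratio of -0.81 in fibroblast-like cells, and depth per cell and the mix of clusters are the technical explanations weighed. After thinning each cell to 1 UMI number the median was -0.76, which keeps 93.8% of its size, against under 25% set for depth. Random thinning leaves the expected composition of a cell unchanged and weights the cells equally. The median thus does not rest on the weight of the deepest cells. That outcome was otherwise nearly fixed in advance, so other effects of depth remain untested. The equal-weight mean over 6 clusters was -0.30, 37.0% of the class median, and it lay between the bounds set for either outcome. A different mix of fibroblast-like clusters and a lower level within clusters may both contribute and cannot be told apart, because Col1a1 and Col3a1 are themselves among the top genes of cluster 6. Time after injury stays open as an untested biological explanation, and fibroblast-like cells of other tissue collected with the artery were not tested as a source.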
